A study of Homo sapiens with 2 samples.

How the data were processed

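RNA of purified PBNPs and of their HEK293T producer cells was sequenced, 1 library each. Per the labels' protocols, PBNPs were treated with nuclease before RNA extraction, RNA was treated with DNase I, mRNA was captured with oligo(dT) beads in a stranded mRNA kit, and libraries were amplified by PCR and sequenced as 150 bp paired-end reads on a NovaSeq. Per the submitters' processing notes, fastp, FastQC, HISAT2, SAMtools, featureCounts and the GRCh38 build were used; versions, the annotation release, the strand setting, the treatment of multi-mapping reads and of PCR duplicates, and whether reads or fragments were counted are not given in the sources used here. Because the kit selects poly(A) RNA, RNAs without a tail were measured only as far as they passed this step.

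Per the file headers, the authors deposited raw counts per gene for both libraries in 1 table of 60624 rows, of which 60623 carry Ensembl gene identifiers and 1 is EGFP. Per the file headers, the same table holds the authors' TPM, which scales each count by gene length and to an equal library sum. The TPM ratio of a gene was 0.471 times its CPM ratio for all 5983 genes above 0 in both libraries (tolerance 0.1%), so each gene had the same length in both libraries and TPM acts on ratios as another scaling. The lengths implied by the TPM equalled GENCODE 29 union exon lengths within 0.1% for 63.7% of genes. They were 6689 nt for PEG10 and 720 nt for EGFP. Gene symbols came from a names table (60295 identifiers matched), and biotypes and GRCh38 coordinates from GENCODE 29 (58516 identifiers matched). No row without a gene was present, and 0 columns of the table were left unused.

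Counts were divided by the library total (CPM). The main rule, fixed before the data were examined, took genes with at least 10 counts over both libraries whose ratio of CPM had a 95% interval (exact conditional binomial) wholly beyond 2-fold. Shares have exact Clopper-Pearson 95% intervals. No p-value was computed, as 1 library per group gives no spread between replicates. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The low counts of the PBNP library showed that reads came in clusters, so an interval over PBNP counts divided by the cluster size was added after the data were examined. The size, 62, was the median PBNP count of 873 genes with at most 99 producer and at least 10 PBNP counts. The level a count of 0 allows in PBNPs was set at 3 clusters, 186 counts or 220 CPM; 3 single counts would be 3.55 CPM. Genes at 0 in either library are given by the bound of the interval over read clusters where this excludes 1, and by counts otherwise. Log2 ratios of single genes, used for list medians, had 0.5 counts added in each library.

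For each of 33 gene lists fixed before the data were examined, counts were summed over members, and the median log2 ratio of members with at least 10 counts was set against 10000 random lists of the same size matched on mean log2 CPM of both libraries in 20 bins. Percentiles of at least 97.5 or at most 2.5 were taken as the ends, for lists with at least 5 such members; they describe these libraries and are not tests. Further marker lists of mucosal epithelium, plasma cells, salivary gland, pancreas, lung and muscle were written after marker genes of some of these tissues had been seen, and members already seen were left out of their tests.

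Named genes were PEG10 and genes taken from the 10 genes with the highest and the 10 with the lowest near bound of the interval over reads among genes with at least 100 counts, the 5 at each end among genes with a mean of at least 100 CPM, the 5 largest shares of each library, and in each list the members with the highest and lowest ratio and the largest share. Other members that passed 2-fold over read clusters were named after their values were seen. EGFP was named as the reporter row.

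Alternatives planned before the data were examined were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without mitochondrially encoded genes or without PEG10, other filters and fold limits, other pseudocounts, other matching of random lists and thinning of the deeper library. Both tools were used only for scaling. TMM moved every log2 ratio by -0.60, DESeq2 by -0.52 and the TPM by -1.09, and the ratios above are relative to the library total. The TMM and DESeq2 factors rest on genes with counts in both libraries. The interval over read clusters, the TPM ratios and the summed list ratios against random lists were added later.

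The rules were tested on simulated data with the real genes, producer composition and totals. With independent reads, the interval over reads recovered 100 of 100 raised and 100 of 100 lowered genes at 4-fold, with 2 and 3 unaltered genes passing among 18161 genes. With read clusters, it recovered 89 and 80 among 18044 genes, with 1523 and 6158 unaltered genes passing, and the interval over read clusters recovered 44 and 5, with 97 and 0 passing. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used, with random seed 20261201.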

Results

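The series asked which transcripts are packaged in protein-based nanoparticles (PBNPs) built from PEG10, and how their make-up compares with that of the cells that release them. PEG10 is an imprinted gene derived from a retrotransposon; its Gag-like protein assembles into capsids. RNA was sequenced from 1 preparation of purified, nuclease-treated PBNPs and from 1 culture of the HEK293T producer cells, a line derived from human embryonic kidney. The producer library held 17262809 gene counts and the PBNP library 845331, so the producer library was 20.4-fold deeper. With 1 library per group no difference below has a replicate check, and no test between the groups was possible; each ratio compares these 2 libraries. Ratios are PBNP over producer CPM, counts scaled by the library's own total.

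Counts in the PBNP library were not spread as independent reads. Among 873 genes with at most 99 producer counts and at least 10 PBNP counts, the median PBNP count was 62. Over all genes, the fullest bin of counts was 1 to 9 (1097 genes). Above it the number of genes peaked at 50 to 59 (521 genes) and again at 110 to 119 (308 genes), with fewer at 10 to 19 (197 genes) and at 80 to 89 (260 genes). Of the 2492 genes with 1000 to below 2000 producer counts, 45.1% had no PBNP count at all. For this reason each ratio below is given with a 95% interval in which every 62 PBNP counts are taken as 1 unit, called a read cluster, which leaves 13634 units in the PBNP library. This interval was chosen after the data were examined, and like every interval here it covers counting error only. A count of 0 in PBNPs allows a level of up to 3 read clusters, or 220 CPM, and a count of 0 in the producer cells up to 3 counts, or 0.174 CPM. For genes at 0 whose interval over read clusters lay wholly above or below 1, the bound of this interval is given. These bounds come from the interval, not from the floors just given, and are wider. Other genes at 0 in PBNPs are given by their counts alone; their upper bounds lay above 1, so no lower level is shown for them.

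**Figure D1:**
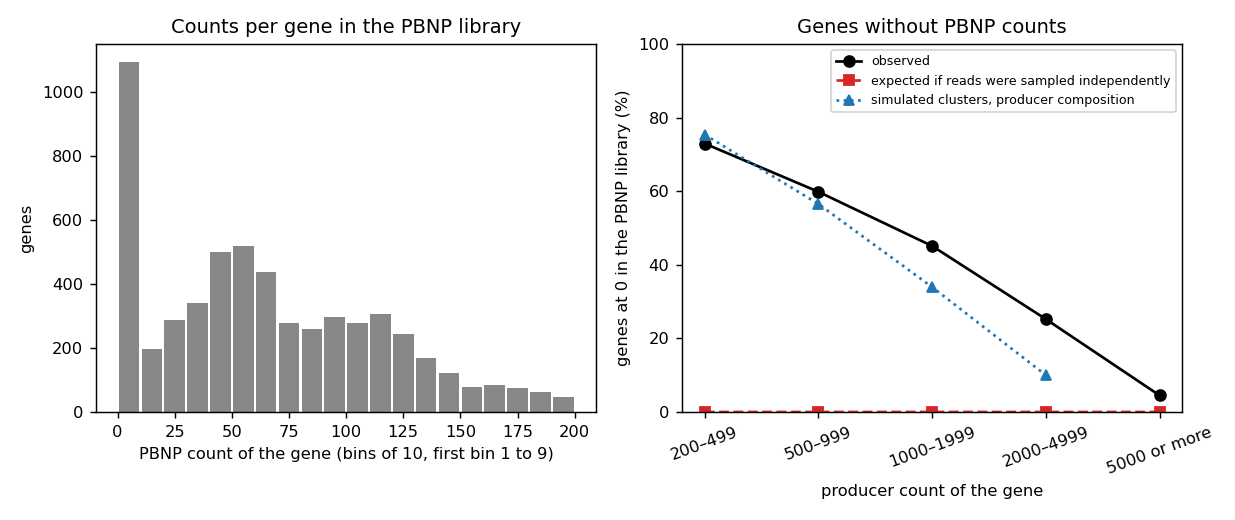
Left, number of genes (vertical axis) by their count in the PBNP library (horizontal axis, bins of 10 counts). Right, percent of genes with no PBNP count (vertical axis) by producer count (horizontal axis), as observed (circles), under independent sampling of reads (squares) and in a simulated library of read clusters with the composition of the producer cells (triangles, not simulated for the top bin). The observed share went from 72.9% of genes at 200 to 499 producer counts to 4.49% at 5000 or more, where independent reads leave almost none.

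PEG10 mRNA had the most counts of any gene in both libraries and made up a larger share of the PBNP RNA. PEG10 (ENSG00000242265, chromosome 7, 94656325 to 94669695, GRCh38) had 401706 counts in the producer cells, 2.33% of the library (exact Clopper-Pearson interval 2.32 to 2.33). In PBNPs it had 42950 counts, 5.08% of the library (5.03 to 5.13). The ratio of CPM was 2.18, with an interval of 2.16 to 2.21 over reads and of 2.02 to 2.35 over read clusters. The table also held a row for EGFP, the enhanced green fluorescent protein reporter, with 0.808% of the producer counts (0.804 to 0.812) and 1.04% of the PBNP counts (1.02 to 1.07). Its ratio was 1.29 (1.09 to 1.52 over read clusters), and 0.852 or 0.902 with TMM or DESeq2 scaling. PEG10 counts per EGFP count were 2.88 in the producer cells and 4.86 in PBNPs. The PEG10 row sums every read assigned to the gene, so transcripts of the endogenous locus and of any introduced PEG10 construct were not separated. The PEG10 ratio was 1.44 with TMM factors and 1.03 on the authors' TPM scale (11853 TPM in the producer cells and 12180 TPM in PBNPs), on which short noncoding RNAs took a large part of the PBNP total.

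**Figure D2:**
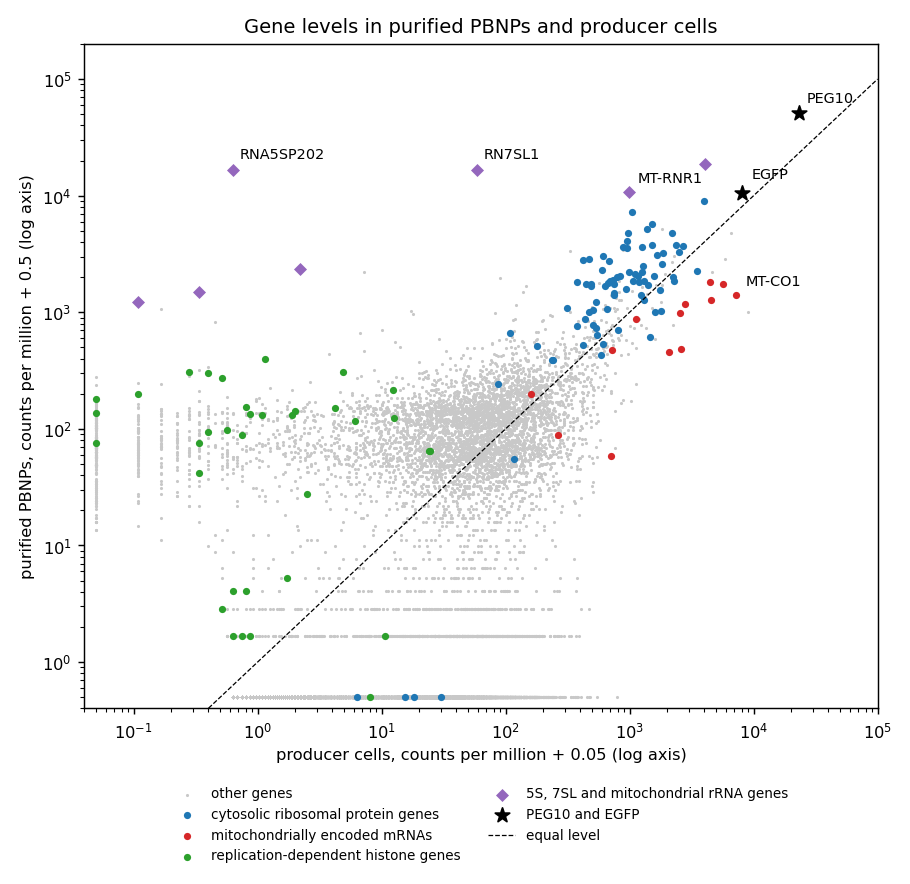
Level of each gene with at least 10 counts over both libraries in the producer cells (horizontal axis, CPM plus 0.05, log scale) and in purified PBNPs (vertical axis, CPM plus 0.5, log scale); each point is 1 gene and the dashed line marks equal levels. PEG10 lay above the line at a ratio of 2.18, 5S, 7SL and mitochondrial rRNA genes lay farther above it, and most mitochondrially encoded mRNAs lay below it; the band along the bottom holds genes without PBNP counts.

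Noncoding RNAs made up more of the PBNP library than of the producer library. Protein-coding genes held 95.1% of the producer counts and 84.7% of the PBNP counts, a ratio of 0.891 (0.875 to 0.908). The mitochondrial ribosomal RNAs held 0.506% and 2.96%, a ratio of 5.86 (5.30 to 6.46). Annotated rRNA genes and rRNA pseudogenes went from 43 producer counts to 15972 PBNP counts, or 1.89% of the PBNP library, at a ratio of 7585 (5484 to 10752). The class with 7SL, the RNA of the signal recognition particle, and Y RNAs held 0.00846% of the producer counts and 2.13% of the PBNP counts, a ratio of 251 (221 to 285). Ratios were 16.6 for snoRNA (12.6 to 21.5), 56.7 for the spliceosomal snRNA class (33.4 to 88.4), 70.2 for BCYRN1, a neuronal cytoplasmic RNA related to 7SL (34.7 to 139), 2.53 for processed pseudogenes (2.23 to 2.87) and 42.2 for immunoglobulin genes (31.1 to 56.6). The ratio of 1.41 for long noncoding RNA (1.29 to 1.55) was 0.932 with TMM and 0.987 with DESeq2 scaling. As the authors' TPM divides by gene length, the rRNA class took 25.2% of the PBNP total on that scale and protein-coding genes 40.6%, against 86.3% in the producer cells.

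**Figure D3:**
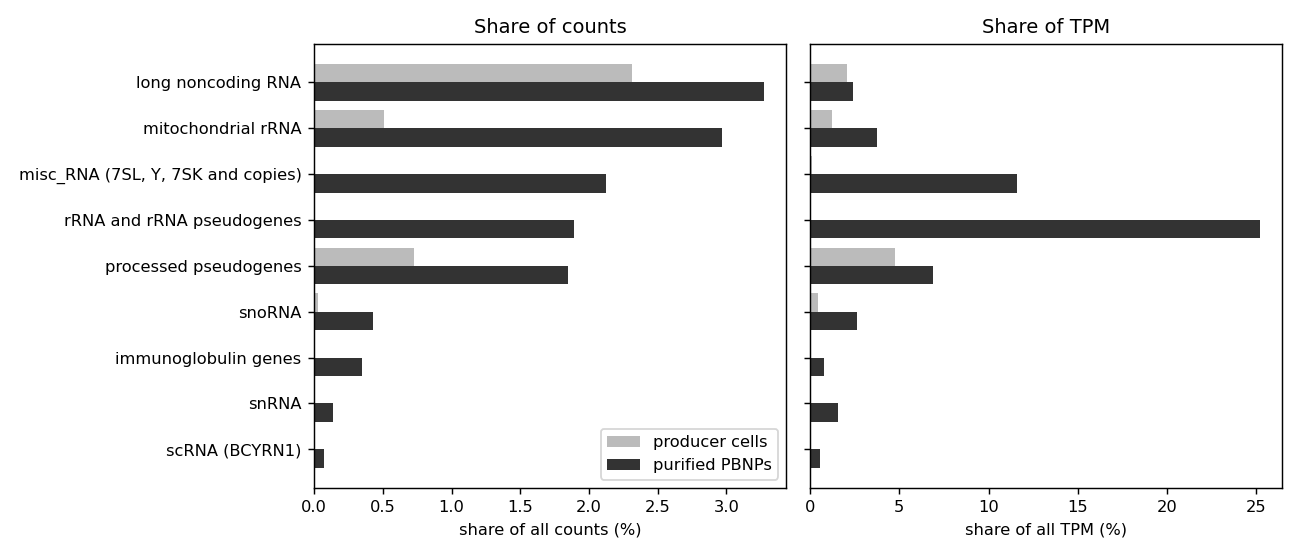
Share of all counts (left, percent) and of all TPM (right, percent) taken by each noncoding or pseudogene class in the producer cells (light bars) and in purified PBNPs (dark bars), 1 library each; the axes of the panels differ in range. The rRNA class took 1.89% of the PBNP counts and 25.2% of the PBNP TPM.

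By counts, the most abundant PBNP transcripts after PEG10 were noncoding. MT-RNR2, the large mitochondrial rRNA (mitochondrial genome, 1671 to 3229), had 70329 producer and 15921 PBNP counts, a ratio of 4.62 (4.08 to 5.23). RN7SL1, a 7SL gene (chromosome 14, 49586580 to 49586878), had 1011 and 14159 counts, a ratio of 286 (246 to 330). RNA5SP202, annotated as a 5S rRNA pseudogene (chromosome 6, 4427963 to 4428081), had 10 and 14123 counts, a ratio of 28841 (15413 to 61013). MT-RNR1, the small mitochondrial rRNA (mitochondrial genome, 648 to 1601), had 17009 and 9141 counts, a ratio of 10.97 (9.24 to 12.9). In the producer cells the leading transcripts after PEG10 were XIST, EGFP, MT-CO1 and EEF1A1, which encodes a translation elongation factor and had a ratio of 0.718 (0.556 to 0.919). Genes for 5S and 7SL RNA have many near-identical copies, and the treatment of multi-mapping reads is not given in the sources used here. Their counts are thus uncertain for the named copy and for the RNA family as a whole.

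Ranked by the lower bound of the interval over reads, the genes farthest above the producer cells were again short structural RNAs, along with several genes that the producer cells hardly expressed. RNA5SP202 led, followed by RNA5S9, a 5S rRNA gene with 1 producer and 1030 PBNP counts (ratio 21034, 3373 to 899533). The 7SL copies RN7SL5P (5 and 1270 counts) and RN7SL3 (37 and 1996 counts) had ratios of 5187 (1844 to 17269) and 1102 (660 to 1807), and the rRNA gene ENSG00000275757 (7 and 702 counts) one of 2048 (704 to 6053). DMBT1, which encodes a mucosal scavenger protein, had 2 and 905 counts, a ratio of 9241 (2208 to 85578). No producer count was found for the immunoglobulin genes IGKV2-30 (234 PBNP counts) and IGLC3 (201), for the histone gene H2AC14 (152) or for DENND2D (150), and the lower bounds of their ratios over read clusters were 836, 523, 238 and 238. Markers of mucosal epithelium and of plasma cells were also detected in the PBNP library more often than random genes of the same producer level, with 19 of 43 and 8 of 16 markers at 10 or more PBNP counts. In the deeper producer library, 14 and 9 of these markers had 10 or more counts.

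XIST and several mitochondrial mRNAs were among the abundant transcripts that were lower in PBNPs. XIST, the long noncoding RNA that coats the inactive X chromosome (chromosome X, 73820651 to 73852723), had 156447 producer and 853 PBNP counts, a ratio of 0.111 (0.0619 to 0.190). MT-CO1, a subunit of cytochrome c oxidase, had 125206 and 1191 counts, a ratio of 0.194 (0.116 to 0.300). The 10 genes with the lowest upper bound over reads all had no PBNP count, but with so few read clusters their differences are bounded only loosely. MORF4L2, a chromatin factor with 13653 producer counts, had an upper bound of 0.342 over read clusters, and ADAMTS1, a secreted metalloprotease with 9469, one of 0.493. NUCKS1, the cell cycle inhibitor gene CDKN1A and KCTD12, with 8241, 8170 and 7791 producer counts, had upper bounds of 0.567, 0.572 and 0.600, which did not pass 2-fold. For KIF1A, FAM168B, MCL1 and RBBP7, with 6611 to 6339 producer counts, the upper bound was 0.707 to 0.737.

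Counted over all genes, 747 of 18534 genes with at least 10 counts over both libraries had a read-cluster interval wholly above 2-fold, and 8 had one wholly below. The 8 lower genes were XIST, MORF4L2, ADAMTS1 and the mitochondrial MT-CO1, MT-CO3, MT-ND2, MT-ND4 and MT-ND5, of which MT-CO3, MT-ND2, MT-ND4 and MT-ND5 were named after their values were seen. Of the 747 higher genes, 375 were protein-coding, 101 lincRNA, 65 processed pseudogenes and 64 antisense genes. The use of strand in counting is not given in the sources used here, so antisense genes are uncertain. A gene with few producer counts could pass on about 1 read cluster, as LYZ did (9 and 89 counts, lower bound 3.21). At 10 or more PBNP counts, 270 genes had no producer count and 271 had 1 to 9, with median PBNP counts of 62.5 and 63. Many of the 747 may thus rest on about 1 read cluster. In a simulated library of read clusters with no gene altered, 92 genes passed as higher and 0 as lower, and of 100 genes raised and 100 lowered 4-fold the rule recovered 44 and 5. The interval over reads, fixed before the data were examined, gave 2220 higher and 7259 lower genes, but 1708 and 5885 in the simulated library with no gene altered. With TMM scaling the counts were 629 higher and 48 lower over read clusters, and the intervals of PEG10, GAPDH, ATP5PO, SSR4, CD63, AHNAK, TMSB10, DUSP1, SNHG5 and HBB, which passed 2-fold in the main setting, no longer passed. With DESeq2 scaling the same genes did not pass. On the TPM scale MT-RNR2, KRT8, KRT18, ZNF544, HLA-DRA and LYZ also did not pass, and the counts were 555 higher and 114 lower over read clusters, and 1386 and 9703 over reads.

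Genes for cytosolic ribosomal proteins, which carry short and abundant mRNAs, stood higher in PBNPs as a group. The 79 genes held 7.96% of the producer counts and 16.03% of the PBNP counts, a ratio of 2.01 (1.93 to 2.10), and 18 passed 2-fold as higher and 0 as lower. RPL41 had the highest ratio, 6.84 (5.54 to 8.32), and RPS2 the largest share, with 68848 producer and 7573 PBNP counts and a ratio of 2.25 (1.86 to 2.68). In all, 4 members were at 0 in PBNPs. The median log2 ratio of the group, 0.95, was above all of 10000 random lists of equal size and expression (percentile 100). The summed ratio was 1.33 with TMM scaling and 1.02 on the TPM scale. With TMM scaling, RPLP1, RPS16, RPL37, RPS20, RPL12, RPL38, RPL35, RPS14, RPS21 and RPS26 no longer passed 2-fold. On the TPM scale, only RPL41, RPL30 and RPLP2 of the 18 still passed. Processed pseudogenes of these genes can share their reads.

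Translation factors lay lower, and mitochondrial ribosomal protein genes between. The summed ratio of translation factors was 0.707 (0.615 to 0.809), with EIF3C at 3.83 (0.0689 to 15.3) and EIF3M at 3631 producer and no PBNP counts. None of the 29 translation factors tested passed 2-fold. For genes of mitochondrial ribosomal proteins it was 1.55 (1.12 to 2.10; 1.02 with TMM, 1.08 with DESeq2 and 0.717 with TPM), from MRPL32 at 6.62 (0.846 to 25.5) to MRPL4 with 1240 producer and no PBNP counts; MRPL37 held the largest share, at 1.86 (0.523 to 4.93). No member passed 2-fold. This list's median log2 ratio was 0.38, at percentile 97.8, and its mean was -1.52.

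**Figure D4:**
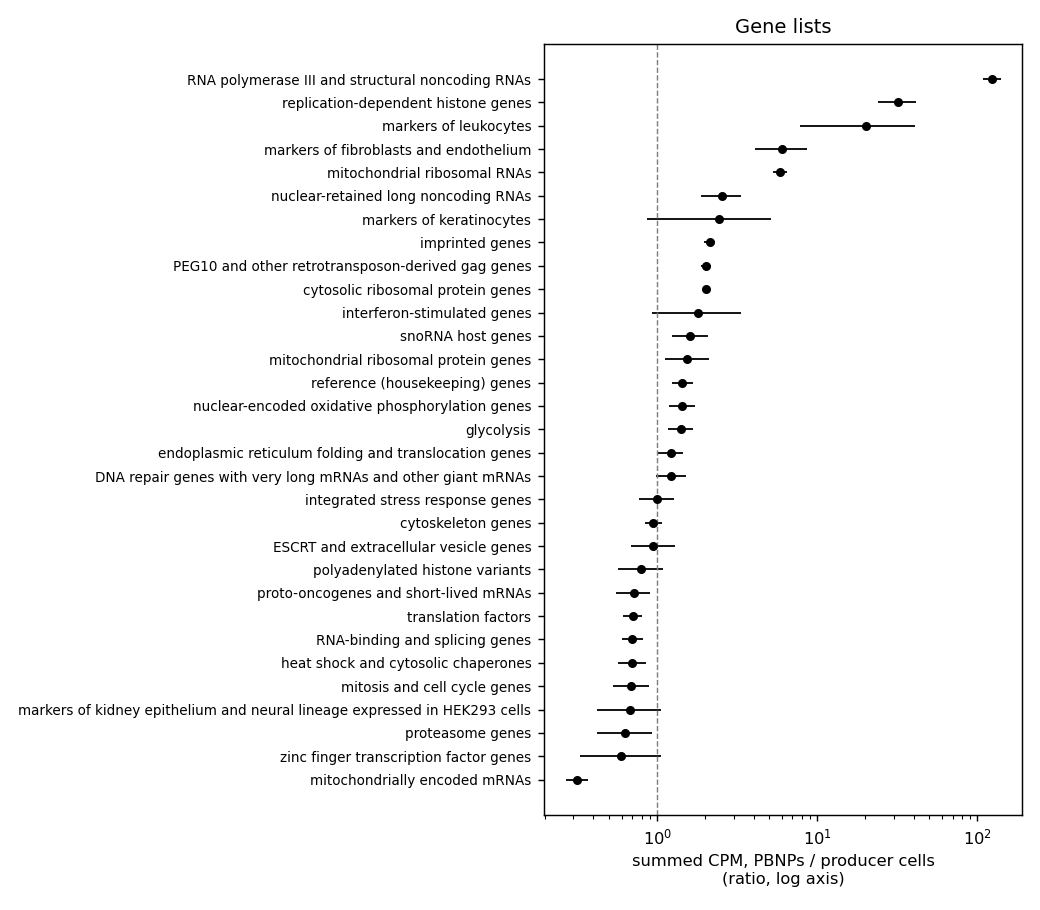
Ratio of summed CPM, PBNPs over producer cells (horizontal axis, log scale), for each gene list with at least 5 members at 10 or more counts and for the mitochondrial ribosomal RNAs; lines are 95% intervals over read clusters, from 1 library per group, and the dashed line marks equal levels. RNA polymerase III and structural RNAs (123) and replication-dependent histone genes (31.8) lay highest and mitochondrially encoded mRNAs (0.318) lowest.

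Transcripts of the mitochondrial genome split by kind. The 13 mitochondrially encoded mRNAs held 3.49% of the producer counts and 1.11% of the PBNP counts, a ratio of 0.318 (0.269 to 0.372), while the mitochondrial rRNAs MT-RNR1 and MT-RNR2 were higher by the ratios given above. 5 of the 13 mRNAs passed 2-fold as lower and 0 as higher. MT-ND4L had the lowest ratio, 0.0818 (0.00262 to 0.577), MT-ND6 the highest, 1.23 (0.283 to 4.01), and MT-CO2 the largest PBNP share, at 0.409 (0.266 to 0.606). The list's median lay below nearly all random lists matched on the mean of both libraries (percentile 0.00) and at percentile 15.6 when they were matched on the producer level. Its summed ratio was at percentile 1.23 of producer-matched lists. Nuclear-encoded genes of oxidative phosphorylation had a summed ratio of 1.43 (1.18 to 1.73), which was 0.944 with TMM scaling. NDUFA9, a complex I subunit gene, at 19.7 (4.26 to 62.0), and ATP5PO, an ATP synthase subunit gene, at 8.07 (2.01 to 19.1), passed 2-fold as higher; UQCRC1 held the largest PBNP share, at 3.48 (1.69 to 6.48), and COX7B had 1332 producer and no PBNP counts.

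Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, were higher in PBNPs. Their summed ratio was 31.8 (23.8 to 41.5), and 22 of the 35 genes tested passed 2-fold as higher and 0 as lower. With TMM scaling, H2AC11 and H4C9 no longer passed. H4C3 held the largest share, with 19 producer and 337 PBNP counts and a ratio of 362 (97.2 to 923). H2BC12, the member with the most producer counts, stood at 2.62 (0.0760 to 16.8), and H2BC15 had 138 producer and no PBNP counts. Histone variants with polyadenylated mRNAs stood at 0.792 (0.568 to 1.08), from H2AZ1 at 1.74 (0.918 to 2.82) to H2AX with 2746 producer and no PBNP counts. None of the 10 variants passed 2-fold. The list of RNA polymerase III and structural noncoding RNAs had a summed ratio of 123 (109 to 140), with 7 of 9 members higher, among them RNU1-1, the U1 snRNA, at 101 (44.6 to 197), SNORD3A, the U3 snoRNA, at 21.6 (14.3 to 31.9) and RNY3, a Y RNA, at 1613 (16.1 to 99387) on 1 producer and 79 PBNP counts. VTRNA1-3, a vault RNA, had 22 producer and no PBNP counts. Medians of the histone and structural RNA lists were at percentile 100. Many histone genes are near-identical, so single members are uncertain.

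Nuclear long noncoding RNAs differed from each other. The summed ratio of 2.55 (1.89 to 3.34) came from MALAT1, a nuclear speckle RNA that passed 2-fold as higher with 5661 producer and 2827 PBNP counts and a ratio of 10.2 (7.52 to 13.7). NEAT1, the paraspeckle RNA, stood at 1.10 (0.335 to 3.16), TUG1 had 5158 producer and no PBNP counts (upper bound 0.906), and 8 of the 11 RNAs tested had no PBNP count. NORAD, which was in the list although it is known as a mainly cytoplasmic RNA, had the most producer counts, at 0.353 (0.0424 to 1.26). Host genes of snoRNAs stood at 1.61 (1.23 to 2.09; 1.06 with TMM and 0.705 with TPM), with SNHG5 at 4.26 (2.26 to 7.65), GAS5 at 1.72 (0.962 to 2.84) and SNHG15 at 1601 producer and no PBNP counts.

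Other capsid-like genes were too scarce in PBNPs for most to be set apart from PEG10. Of 23 tested genes derived from retrotransposon gag sequences, 15 had no PBNP count, and the list's summed ratio of 2.03 (1.88 to 2.18) came mostly from PEG10. PNMA8B, with 0 producer and 91 PBNP counts, had a lower bound of 32.5 on about 1 read cluster. PNMA8A had 1979 producer and no PBNP counts, and ZCCHC12 a ratio of 0.216 (0.0405 to 0.574). The imprinted genes likewise summed to 2.12 (1.97 to 2.29) through PEG10, with 11 of 18 genes at 0 in PBNPs. SGCE, the neighbour of PEG10, had a ratio of 4.67 (0.112 to 25.04), and ZDBF2 had 1314 producer and no PBNP counts. Genes of ESCRT and extracellular vesicles stood at 0.948 (0.688 to 1.30), with CD63, a tetraspanin of endosomes and exosomes, higher at 4.97 (2.16 to 9.91), PDCD6 at 6.95 (0.337 to 76.9) and SDCBP at 2507 producer and no PBNP counts.

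The following lists lay between 0.948 and 1.44 by library total, and lower with TMM scaling. Glycolysis stood at 1.40 (1.16 to 1.66), led by GAPDH at 2.85 (2.23 to 3.61), with ENO2 at 3189 producer and no PBNP counts. Reference genes stood at 1.44 (1.23 to 1.68), with B2M highest at 3.30 (1.40 to 6.43) and TFRC at 4450 producer and 1 PBNP counts. Genes of endoplasmic reticulum folding stood at 1.22 (1.02 to 1.45), with SSR4 higher at 5.89 (2.57 to 10.7), HSP90B1 at 1.99 (1.19 to 3.10) and STT3B at 3009 producer and no PBNP counts. With TMM scaling these 3 ratios were 0.923, 0.949 and 0.806. Giant mRNAs, DNA repair genes included, stood at 1.22 (0.981 to 1.51; 0.804 with TMM), with BRCA2 at 5.88 (0.595 to 17.9), BRCA1 at 1627 producer and no PBNP counts and DYNC1H1 at 2.27 (1.25 to 3.67); AHNAK, which encodes a giant scaffold protein, passed 2-fold at 3.93 (2.14 to 6.90). Genes of the integrated stress response stood at 0.998 (0.767 to 1.28; 0.658 with TMM and 0.491 with TPM), with DDIT4 at 3.69 (1.65 to 6.86), ATF4 at 0.719 (0.406 to 1.20) and TRIB3 at 634 producer and no PBNP counts. Cytoskeleton genes stood at 0.948 (0.835 to 1.07; 0.625 with TMM), although the keratin genes KRT18, at 7.48 (3.95 to 13.4), and KRT8, at 7.34 (3.81 to 12.9), and the actin-binding TMSB10, at 3.18 (2.001 to 4.65), passed 2-fold as higher. The actin genes ACTB and ACTG1 stood at 1.23 (0.873 to 1.71) and 0.482 (0.323 to 0.684), and RDX had 2698 producer and no PBNP counts.

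Several lists of cell cycle and gene regulation had summed ratios below 1. Proteasome genes stood at 0.628 (0.418 to 0.924), with PSMB6 at 2.43 (0.261 to 7.80), PSMB4 at 1.32 (0.560 to 2.87) and PSMB1 at 2062 producer and no PBNP counts. Heat shock genes and cytosolic chaperones stood at 0.696 (0.565 to 0.849), with HSPE1 at 4.74 (0.987 to 14.1), HSP90AB1 at 0.684 (0.408 to 1.12) and HSPH1 at 2190 producer and 1 PBNP counts. Genes of mitosis and the cell cycle stood at 0.690 (0.526 to 0.884), with CCNE2 at 4.66 (0.646 to 19.4), MCM7 at 1.29 (0.530 to 2.42), MKI67 at 0.567 (0.152 to 1.43) and CDK1 at 2479 producer and no PBNP counts. Genes of RNA binding and splicing stood at 0.701 (0.604 to 0.811), with CLK1 at 2.41 (0.351 to 10.5), HNRNPA1 at 1.11 (0.740 to 1.59) and SRSF10 at 4028 producer and no PBNP counts. Proto-oncogenes and short-lived mRNAs stood at 0.715 (0.552 to 0.904), with GADD45G at 4.49 (0.0890 to 19.8) and JUN at 0.771 (0.394 to 1.33). Zinc finger genes stood at 0.598 (0.329 to 1.06), with ZNF544 at 178 (4.01 to 1408), ZNF721 at 3.80 (0.416 to 12.5) and ZNF664 at 6363 producer and 1 PBNP counts. Markers of kidney epithelium and neural lineage that HEK293 cells express stood at 0.677 (0.420 to 1.06), with NEFM at 0.973 (0.441 to 1.83) and CDH6 at 4 and 18 counts. None of these genes passed 2-fold except ZNF544 and, among the proto-oncogenes, DUSP1 at 4.33 (2.33 to 7.89).

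Markers of cell types other than the producer cells were higher in PBNPs in several lists. Fibroblast and endothelial markers had a summed ratio of 6.02 (4.09 to 8.68), and 5 of 13 passed 2-fold as higher (3 with TMM scaling, where COL1A2 and CDH5 did not pass), among them COL3A1 (501 and 503 counts, ratio 20.5, 8.68 to 40.1) and VWF (9 and 115 counts, ratio 261, 29.6 to 1359). COL1A1 held their largest share, at 3.83 (1.72 to 7.15), FBN1 had 259 producer and no PBNP counts, and the list's median was at percentile 99.98. Leukocyte markers stood at 20.1 (7.82 to 40.6), through CD74 (21 and 189 counts), HLA-DRA (191 and 165) and LYZ (9 and 89), while CD14 had 87 producer and no PBNP counts. Keratinocyte markers stood at 2.45 (0.868 to 5.16), with KRT14 at 5 and 110 counts (ratio 449, 48.2 to 3093), DSP at 1.31 (0.263 to 3.74) and SFN at 141 producer and no PBNP counts. The hepatocyte list stood at 35.4 (4.48 to 142) on TF, the gene of transferrin, alone (35 and 115 counts). Erythroid markers stood at 3.78 (2.74 to 4.998) through HBB, which was itself abundant in the producer cells (15380 counts). Interferon-stimulated genes stood at 1.79 (0.927 to 3.33), with OAS1 (1 and 102 counts), MX2 (3 and 115) and IFITM2 (171 and 193) higher and IFI6 at 812 producer and no PBNP counts.

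Against random lists of equal size and expression, 5 of 30 gene lists lay at the high end by their median ratio: ribosomal proteins, mitochondrial ribosomal proteins, replication-dependent histones, RNA polymerase III RNAs, and fibroblast and endothelial markers. At the low end lay 8 lists: mitochondrially encoded mRNAs, translation factors (percentile 1.54), heat shock genes (0.880), ESCRT and extracellular vesicle genes (1.13), mitosis genes (2.12), cytoskeleton genes (1.96), RNA-binding genes (0.0400) and proto-oncogenes (0.250). The gag-derived genes were at percentile 23.1, imprinted genes at 25.96, snoRNA host genes at 85.7 and nuclear long noncoding RNAs at 12.7. When the random lists were matched on the producer level alone, 10 lists lay at the high end and 0 at the low end, so by the median no low list held under both.

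Fewer genes were detected in PBNPs, and their counts were more concentrated. At 1 or more counts, 28300 genes were detected in the producer cells and 6314 in PBNPs. At 10 or more counts the numbers were 17980 and 5217. Thinned to the PBNP total, the producer library still showed 17782 genes, and thinned to 13634 counts, the number of PBNP read clusters, it showed 5626. The 10 most abundant genes held 7.94% of the producer counts and 15.1% of the PBNP counts, the top 100 held 21.1% and 34.8%, and the top 1000 held 47.6% and 63.9%. These shares were not computed after thinning. With only 13634 read clusters, sampling alone can raise the share of the top genes, so how much of the difference it explains was not tested. Across 18534 genes, the levels of the 2 libraries on the log2(CPM + 1) scale had a Pearson correlation of 0.398 and a Spearman correlation of 0.390; genes are not independent replicates, so no p-value is given. Restricted to the 6179 of these genes with PBNP counts, the Pearson correlation was 0.225.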

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

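The interval over read clusters, the TPM ratios, the thinning to read clusters, the correlation over genes above 0 in PBNPs and the summed ratios against random lists were chosen after the data were examined; all other alternatives were planned. The PEG10 ratio was 1.44 with TMM, 1.52 with DESeq2, 2.25 without PEG10 in the total and 2.18 with the TPM of protein-coding genes. On the TPM scale of all genes, where each ratio is multiplied by 0.471, it was 1.03, with a lower bound of 0.953 over read clusters. The number of higher genes over reads (2220) was 1435 at a stricter limit of 4-fold, 1386 on the shifted TPM scale and 747 with the wider intervals over read clusters. The number of lower genes (7259) was 12123 for a log2(CPM + 1) difference beyond 1 without an interval and 8 over read clusters. Genes detected in the producer cells (28300) were 17782 and 5626 after thinning to the PBNP total and to the read clusters. The correlation across genes (0.398) was 0.336 and 0.480 with pseudocounts of 0.1 and 10, 0.512 without a filter, 0.333 at 100 or more counts and 0.225 over genes above 0 in PBNPs; the cause was not tested. By the median, the 5 lists at the high end of random lists became 10 and the 8 at the low end 0 when random lists were matched on the producer level. By summed ratio against producer-matched lists, 1 list was at the low end, the mitochondrially encoded mRNAs (percentile 1.23). For the other low lists the low end rests on the matching. The median of mitochondrial ribosomal protein genes (0.38) was -0.22 with TMM and -0.14 with DESeq2, and their mean was -1.52; both scalings lower all genes alike. In all, 26 values for the comparisons held and 19 moved, all printed above, and for lists and top shares 126 held, 120 moved and 3 turned sign in a list at an end; the sign turned in some lists away from the ends, such as oxidative phosphorylation, leukocyte markers and imprinted genes. A common scaling leaves the lists' percentiles as they are. No paired analysis was possible because each group has 1 library, which also rules out leaving libraries out. The read clusters limit most the lower genes: at 13634 read clusters, 5 of 100 genes lowered 4-fold were recovered in the simulation. With independent reads at the same totals, the interval over reads recovered 100 of 100.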

Other observations

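All tests in this part were chosen after the values they concern had been seen. Globin genes differed within the erythroid list. HBB, which encodes beta-globin (chromosome 11, 5225464 to 5229395), had 15380 producer counts (891 CPM) and 2879 PBNP counts (3406 CPM), a ratio of 3.82 (2.77 to 5.05 over read clusters). The alpha-globin genes HBA1 and HBA2 had 55 and 94 producer counts and no PBNP counts, HBG2 had 1 producer count, and HBD, HBG1 and HBE1 had none in either library.

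Among protein-coding genes with at least 1000 producer counts, without PEG10 and mitochondrial genes, the shortest genes had the highest ratio, and no steady trend with length followed. In 5 groups of equal size by gene length, the summed ratio was 1.24 (1.19 to 1.28) for the shortest genes (median length 2554 nt), then 0.801, 0.637 and 0.596, and 0.662 (0.622 to 0.703) for the longest (median 11649 nt). Without ribosomal protein genes the groups stood at 0.915 (0.873 to 0.960), 0.638, 0.573, 0.524 and 0.650 (0.610 to 0.691), each below the ratio of 2.01 of ribosomal protein genes. The lengths are those implied by the TPM, which can exceed the length of the mRNA. The shortest of these groups had a median of 2601 nt, and no set of equally short mRNAs was compared. An effect of mRNA length on the ribosomal protein genes is thus not separated.

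PBNP counts per gene peaked at 50 to 59 and again, more weakly, at 110 to 119 (521 and 308 genes), with many genes between the peaks and 1097 genes at 1 to 9 counts. Sampling depth alone is argued against, since 45.1% of genes with 1000 to below 2000 producer counts had no PBNP count. A library grown from few RNA fragments by amplification may account for it: the producer library drawn at 13634 counts showed 5626 genes at 1 or more, 1.08 times the 5217 genes with 10 or more PBNP counts. At 1 or more PBNP counts there were 6314 genes, and 13634 was itself derived from the PBNP counts, so this is a weak check. Such a draw cannot give the 270 of the 5217 genes without producer counts. At 2000 to 4999 producer counts, 25.2% of genes were at 0, against 10% in the simulated library of read clusters. Selective exclusion of single mRNAs cannot be told apart from other variation between genes. Of the genes with 1000 to below 2000 producer counts, 2.15 percentage points more were at 0 than in 1000 draws with the same total for these genes (mean 43.0%, SD 0.968). With the composition of the producer cells, 33.9% were at 0. Of the 2492 genes, 1124 were at 0 and 1150 had 10 or more counts. The rest, with 1 to 9 counts and so far below 1 read cluster, were taken as above 0. The size of the excess depends on this choice. Whether few molecules entered the particles or few survived library preparation stays open.

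RNAs without a poly(A) tail were higher in the PBNP library by very different factors. The lower bound of the 5S ratio (28131, 15422 to 57006, on 11 producer counts) was 372 times the upper bound of the histone ratio (31.8, 23.8 to 41.5), with 7SL between them (338, 295 to 386). Carry-over through the oligo(dT) step by 1 common factor would give equal ratios only if each family's producer counts came from carry-over alone. That was not tested, so the unequal ratios cannot decide on this explanation. A bias toward short RNAs as the whole cause is argued against only for the pair MT-RNR2 (1559 nt) and MT-CO1 (1542 nt). The lower bound of the ratio of the former was 13.6 times the upper bound of the latter. This pair cannot decide for 5S, 7SL and histone RNAs, which it does not include. Their ratios fell as length rose (119 nt for RNA5SP202, 299 nt for RN7SL1, 387 nt for the histone gene H2AC14). MT-RNR1 (954 nt, ratio 10.97) and MT-RNR2 (ratio 4.62) lay below them. A length bias thus stays open for these RNAs. Selective packaging by the particles cannot be told apart from a general property of purified particles or of small RNA inputs, since 0 preparations without PEG10 were among the samples. A mixture of carry-over and length effects may also remain, and was not tested.

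Transcripts of mucosal epithelium and plasma cells were found in the PBNP library. Proportional sampling of the producer cells' RNA is argued against by the summed ratio of 43 mucosal markers, 9.35 with a lower bound of 6.99. A uniform background such as genomic DNA as their whole cause is argued against by the plasma cell markers. Of these, 8 of 16 were detected against a mean of 1.84 in random lists matched on producer counts (percentile 100). Their summed ratio was 19.4 (13.7 to 27.4). Such a background adding to another source is not excluded. Among genes silent in the producer cells, 3.55% of the longest group by exon length were detected, against 1.05% to 1.71% of the shorter groups. RNA of another human tissue in the PBNP library is a candidate source: 19 of the 43 mucosal markers were detected against a mean of 4.13 (percentile 100). However, 14 of all 43 mucosal markers and 9 of the 16 plasma cell markers also had 10 or more counts in the producer library. Among the most abundant, MUC5B (seen before) had 124 producer and 1875 PBNP counts, IGHG1 306 and 817, PIGR 951 and 419, CDH17 64 and 371, AGR2 6 and 287 and MUC2 2075 and 267, whereas salivary gland (1 of 25), pancreas (0 of 11), lung (0 of 15) and muscle markers (3 of 10) were at percentiles 66.7, 32.5, 18.1 and 86.5. Fibroblast and endothelial markers also showed an excess (8 of 14, percentile 99.99), while keratinocyte (95.4), leukocyte (94.5), hepatocyte (68.6) and erythroid markers (39.975) did not reach the high end. The nuclease step would remove free RNA before extraction but not RNA added later, and packaging of these particular transcripts was not tested and stays open, although scarcity in the producer cells alone would raise the matched random lists alike.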
